A study of Mus musculus with 4 samples.

How the data were processed

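Gene expression was measured in mammary tumours of 4 female FVB/N mice aged 26 weeks, all at an early tumour stage. Tumours of 2 mice carrying both the MMTV-cdc25a and the MMTV-neu transgene (Cdc25a;neu) were compared with tumours of 2 mice carrying MMTV-neu alone (neu). Each Cdc25a;neu tumour was hybridised together with 1 neu tumour on 2-colour Agilent oligonucleotide arrays. Every pair was hybridised 2 times with the dyes swapped, giving 4 arrays. Per the labels' protocols, RNA was isolated with an Agilent mini-kit, amplified linearly from oligo-dT primers and labelled with Cy3 or Cy5. The dye of each tumour came from the labels, and ratios are given as Cdc25a;neu over neu throughout.

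Per the file headers, the deposited scanner files hold spot intensities (mean signal and local background median for the green Cy3 and the red Cy5 channel), background-subtracted and dye-normalized processed signals, and log10 ratios of red over green computed from the processed signals. Agilent Feature Extraction 7.2 is named in the submitters' processing notes, while the file headers give version 7.5.1. The authors' deposited value table holds 1 value per spot and array on a natural log scale of red over green. This scale was found by setting it against the scanner's log10 ratio on spots with processed signals above 3000, where the slopes were 2.27, 2.28, 2.28 and 2.29 against an expected 2.30 for natural logarithms, with correlations of 0.982 to 0.992. Direction and log base were settled this way. Column medians were 0.0209, 0.0007, 0.0209 and 0.0078. How that table was centred and normalized is not given in the sources used here, and it served only as an alternative source of values.

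For the main values, the spot intensities were background-corrected by normexp with an offset of 50 and normalized within each array by loess. Control spots had no weight in loess and were left out afterwards, as were spots carrying an outlier flag. Spots of one probe were averaged. A probe was kept if it was well above background in at least 1 channel on at least 2 of the 4 arrays, and the brightest kept probe stood for its gene. Swapped arrays were turned to the same direction, and the 2 arrays of a pair were averaged, because they carry the same RNA extracts. The mouse pair was thus the replicate (n = 2), and the dye swap was technical. Each of the 4 arrays lay on its own slide, so slide could not be tested as a batch.

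Of 41174 probes outside controls, 18392 were named through their accession, 1524 through a current symbol and 961 through a synonym in an annotation table of the mouse assembly GRCm38.p6. The other 20297 probes kept the array's own name. The files name no genome build, so the table served only for names, chromosomes and the order of genes. After the filter, 37173 probes gave 32656 genes or transcripts, 15320 of them with a current symbol. For 3876 genes several probes were kept, and disagreement between them is given where such a gene is named.

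Changes were tested with limma 3.58.1 (R 4.3.3) as the mean of the 2 pair ratios against 0, two-sided, with eBayes and Benjamini-Hochberg adjustment at 0.05 over all genes. The genes named are Cdc25a and Erbb2, then up to 12 per direction that passed. As none passed, the places were filled with named genes of the same sign on all 4 arrays and a log2 ratio of at least 1 in size in both pairs, ranked by the smaller of the 2. For each gene list that passed, and each pathway list described, the 4 measured members with the largest mean log2 ratio in size are named, and for disagreement of the pairs the 4 genes that went opposite ways most. Some items these rules would name are not reported here. Gene lists of pathways and cell type markers were tested with camera at a preset inter-gene correlation of 0.01. Chromosomes and 10 Mb windows with at least 10 measured genes were tested the same way. At the preset correlation these p-values measure spread between genes, not between mice, so they do not cover differences between animals. With an estimated correlation, camera rests on the spread between 2 pairs and could hardly call any list or window. These tests, lists and naming rules and most alternatives were fixed before the data were examined. Random lists of equal size, matched on mean signal in 20 bins, were drawn 10000 times. SDs given with log2 ratios are between the 2 pairs.

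The procedure was tested on simulated data with 32656 genes in this comparison of 2 pairs. In them 200 genes were changed by 1 or 2 on the log2 scale. The genes of the G1/S list were shifted up as well and left out of the false calls. With the gene-to-gene spread estimated from the arrays, none (0) of 100 genes changed by 1 on the log2 scale and 69 of 100 changed by 2 were recovered, with 11 false calls. With an equal spread for every gene, all 100 of each size were recovered, with 16 false calls. Recovery also depends on how many genes change, so these shares need not hold for the arrays. The number of pairs limits the precision of every value. Alternatives covered background correction, normalization, the filter on dim probes, outlier flags, the choice of probe, the treatment of technical replicates, separate-channel values per mouse, the variance model, the threshold, the source of values, left-out arrays and pairs, the list test and the window size.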

Results

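Tumours were compared to find which genes change when the phosphatase Cdc25a, which removes inhibitory phosphates from cyclin-dependent kinases and so promotes cell cycle entry, is over-expressed in mammary tumours driven by neu. Neu is the rodent name of the receptor tyrosine kinase Erbb2, and both transgenes were expressed from the mammary tumour virus promoter (MMTV). The data came from 4 arrays carrying 41534 spots outside controls, with 2 mouse pairs, each of 1 mouse per genotype, and both dye orientations for each pair. Between 78.5% and 92.3% of spots were well above background in the green channel and between 82.7% and 87.9% in the red channel. The median spot signal was 98.3 to 162.4 in green and 161.03 to 202.9 in red, against background medians of 42 to 44 and 61 to 62. Outlier flags fell on 9 to 87 spots per array.

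The Cdc25a probe did not differ between the genotypes, with a mean log2 ratio of 0.05 ± 0.06 (SD, n = 2 pairs; limma adjusted p = 0.781). The labels do not say whether the transgene carries the sequence of this probe, so the value checks nothing about the transgene. A second kept Cdc25a probe gave 0.11. Erbb2 gave 0.65 ± 0.28 in the mean, at 0.45 in pair 1 and 0.85 in pair 2, and did not pass the test (adjusted p = 0.490). Whether its probe reads the neu transgene is not given in the sources used here either.

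Differences that went the same way in both pairs were ranked among genes with a current symbol. The largest in Cdc25a;neu tumours were lower values of the fat cell genes Cfd and Fabp4 and of Ly6d. Beside these stood higher values of a secreted gland protein and a retinol-binding protein. Cfd, the complement factor adipsin made by fat cells, was 11.7-fold lower, with log2 ratios of -3.55 in pair 1 and -3.54 in pair 2. Its probe was well above background on 3 of the 4 arrays in the Cdc25a;neu channel and on all 4 in the neu channel, and its mean log2 ratio ranged from -4.80 to -3.32 over the alternatives, left-out arrays included, so the fold is approximate. Ly6d, a surface protein of luminal and squamous epithelium, was at -2.74 ± 0.26, and Fabp4, the fatty acid carrier of fat cells, at -2.71 ± 0.49. The luminal epithelium list, which holds Ly6d, did not pass (median -0.06, camera adjusted p = 0.341). The 3 kept Fabp4 probes ranged from -2.71 to -0.74. In the higher direction, Dcpp1, a secreted protein of salivary glands and the reproductive tract, was 10.2-fold higher at 3.35 ± 0.01, and its mean ranged from 3.22 to 4.25 over the alternatives. The SD between the pairs leaves out this dependence on processing. The unnamed probes LOC212871, NAP019952-001 and BC059096, chosen after their values were seen, gave 3.47, 3.29 and 3.04. Dcpp1 has near-identical gene copies, so the member of this family that was measured is uncertain. Rbp7, a retinol-binding protein, was at 2.39 ± 0.08, with 1.94 for its second kept probe.

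None of these differences passed the gene test: 0 of 32656 genes had an adjusted p under 0.05 in limma, where the lowest adjusted p was 0.224. At an unadjusted p under 0.05, 3147 genes were found, 1274 higher and 1873 lower, against 1632.8 expected by chance. This excess depended on the fit, with 187 genes under eBayes with trend and robust and 1038 with separate-channel values per mouse without a replicate block. Fits that treated the 4 arrays as units called 888 genes as if independent and 910 with the pair as a random block, which count technical repeats as replicates. Median centring in place of loess called 999, with a lowest limma adjusted p of 2.38e-52, which is implausible from 2 pairs. The other named genes with lower values, none passing, were Sp110 (-1.90 ± 0.05), the ephrin receptor Epha2 (-1.73 ± 0.06), Gdpd3 (-1.69 ± 0.09), Tmem82 (-1.98 ± 0.54), the glucocorticoid-induced leucine zipper gene Tsc22d3 (-1.53 ± 0.13), the lipolysis inhibitor G0s2 (-1.35 ± 0.09) and the noradrenaline transporter Slc6a2 (-1.64 ± 0.64). Car3 and Adipoq, both abundant in fat, gave -2.19 ± 1.12 and -1.91 ± 0.85, and the second kept Car3 probe gave -0.02. The named genes with higher values were the membrane glycoprotein Emb (1.67 ± 0.54, and 0.92 for its other probe) and Clca3a1, of the calcium-activated chloride channel regulator family (1.81 ± 0.83).

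The remaining 8 of the 12 named higher genes belonged to a set of 141 genes whose ratios on all 4 arrays nearly equalled each other. This set, defined after the values were seen as genes at 2-fold or more with at least 10 others within 0.25 on every array, had median log2 ratios of 1.04 in pair 1 and 1.55 in pair 2. The 8 genes were Tpra1 (1.47 ± 0.38), Brinp1 (1.45 ± 0.36), Ica1l (1.49 ± 0.41), Olfr1295 (1.45 ± 0.39), Wnt10a (1.39 ± 0.31), Caap1 (1.43 ± 0.37), Chil3 (1.46 ± 0.42) and Ilf2 (1.43 ± 0.37). The second kept Caap1 probe gave -0.14. The set held 15 olfactory or vomeronasal receptor genes or pseudogenes, with a median log2 signal of 11.3 against 7.66 for the other measured receptors of these families. Of the 47 named genes at 2-fold or more in both pairs and higher on all 4 arrays, 40 lay in the set, while none (0) of the 22 lower ones did. The higher genes outside the set included Dcpp1, Rbp7, Emb and Clca3a1 and, named after their values were seen, Clca3a2 (1.53) and Ceacam10 (1.56).

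**Figure D1:**
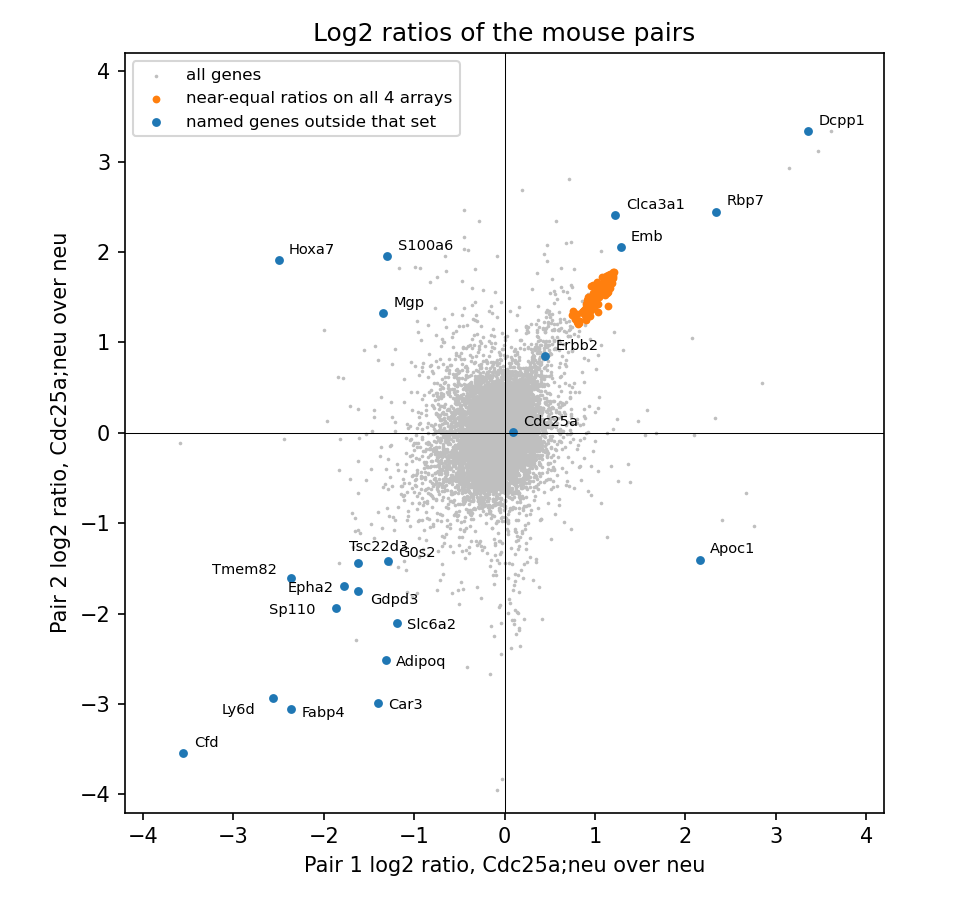
Log2 ratio of Cdc25a;neu over neu for each of 32656 genes in mouse pair 1 (horizontal axis) and mouse pair 2 (vertical axis). Grey points are all genes, orange points the 141 genes with near-equal ratios on all 4 arrays, and blue points the named genes outside that set. Cfd lies at -3.55 and -3.54, and Dcpp1 at 3.36 and 3.34.

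Proliferation genes were higher in Cdc25a;neu tumours of both pairs. The list of G1/S and DNA replication genes shifted up, with a median log2 ratio of 0.17 in pair 1 and 0.20 in pair 2 (camera adjusted p = 2.43e-08, and adjusted p = 0.816 with an estimated correlation), and 27 of its 41 measured members were higher in both pairs against 4 lower in both. Among its members, the primase subunit Prim1 gave 0.50 ± 0.03, the replicative helicase subunits Mcm7 and Mcm6 gave 0.46 ± 0.05 and 0.46 ± 0.01, and the thymidylate synthase Tyms gave 0.44 ± 0.22. Adjusted over the list alone, 5 members passed (Prim1, Mcm7, Mcm6, Mcm3 and Tk1, chosen for naming by this count), and over all genes 0 did. Here and below, this adjustment was made for each of the 29 lists separately, without correction across lists. Mcm3 gave 0.415, with 0.123 for another probe. The G2/M and mitosis list also shifted up, at 0.23 in pair 1 and 0.09 in pair 2 (adjusted p = 2.86e-07, and adjusted p = 0.816 with an estimated correlation), with 19 of 35 members higher in both pairs and 1 lower in both. Its members with the largest ratios were Ect2 (0.71 ± 0.04, with 0.06 for another probe), Kif20a (0.61 ± 0.08), Ccnb2 (0.56 ± 0.23) and Cdca3 (0.48 ± 0.19, with 0.14 for another probe). Ect2 and Kif20a act in cytokinesis and passed when adjusted over the list alone. The DNA damage and checkpoint list shifted up by less, with medians of 0.07 and 0.06 (adjusted p = 0.0169, and adjusted p = 0.816 with an estimated correlation), led by Brca2 (0.50 ± 0.13, with 0.07 for another probe), Exo1 (0.33 ± 0.12), H2ax (0.24 ± 0.09) and Blm (0.23 ± 0.01). Its call was lost without the Cy5 array of pair 1, named for the dye of the Cdc25a;neu tumour (median 0.06, adjusted p = 0.0625), and without the Cy3 array of pair 2 (median 0.03, adjusted p = 0.0899). It was also lost, at medians of 0.08, with the scanner's log ratio (adjusted p = 0.052) and with its processed signals and loess (adjusted p = 0.0506). The list of the CDC25 family and CDK regulators did not pass (median 0.05, adjusted p = 0.419), although it did with median centring in place of loess (median 0.10, adjusted p = 0.0404). Its largest member, Ccnd2 at 1.31 ± 0.38, lay in the set with near-equal ratios and had another probe at 0.01. The next were Cdkn1c (-0.52 ± 0.01), Cdkn1a (0.45 ± 0.31) and Cdkn2b (0.34 ± 0.73). The p53 target list did not pass either (median 0.01, adjusted p = 0.853, with the test on the lower side although median and mean lay above 0), and its largest members were Tnfrsf10b (1.34, in the near-equal set, with another probe at -0.12), Trp53inp1 (-0.69), Plk2 (-0.46) and Cdkn1a.

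Genes of the adipocyte list were lower. The list shifted down, with medians of -0.25 in pair 1 and -0.76 in pair 2 (camera adjusted p = 6.86e-07, and adjusted p = 0.816 with an estimated correlation), and 16 of 21 members were lower in both pairs against 2 higher in both. Its largest members were Cfd, Fabp4, Car3 and Adipoq, given above. Adjusted over the list alone, 3 members passed, Cfd, Fabp4 and the triglyceride lipase Pnpla2 (-0.57, with -0.14 for another probe). The further list of 20 measured fat cell genes, added after the first result and before its own values were seen, had medians of -0.05 in pair 1 and -0.15 in pair 2, with 11 genes lower and 5 higher in both pairs, and the difference between the lists was not tested. The skeletal muscle list was also called as shifted down (adjusted p = 0.0134, and adjusted p = 0.864 with an estimated correlation), but its median was 0.03 in pair 1 and -0.89 in pair 2. The myosin light chain Myl1, the troponins Tnni2 and Tnnc2 and the myosin-binding protein Mybpc2 lay between -2.38 and -1.83 in pair 2 and between -0.26 and 0.07 in pair 1. The endothelium list shifted up slightly, at 0.03 and 0.08 (adjusted p = 0.0134, and adjusted p = 0.816 with an estimated correlation), and 15 of 22 members were higher in both pairs. Kdr, Robo4, Cd34 and Flt4 gave 0.26 ± 0.02, 0.15 ± 0.05, 0.15 ± 0.28 and 0.13 ± 0.14. The endothelium call was lost without the Cy3 array of pair 1 (adjusted p = 0.115) and without the Cy3 array of pair 2 (adjusted p = 0.161).

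Interferon-stimulated genes were lower, by more in pair 2 than in pair 1. The interferon response list had medians of -0.14 in pair 1 and -0.80 in pair 2 (camera adjusted p = 2.93e-10, and adjusted p = 0.816 with an estimated correlation), and 27 of 40 members were lower in both pairs against 1 higher in both. Iigp1, Oasl2, Ifi44 and Gbp3 gave -0.04, -0.75, -0.71 and -0.51 in pair 1 and -2.45, -1.74, -1.63 and -1.74 in pair 2. The antigen presentation list, which shares members with it, had medians of 0.01 and -0.74 (adjusted p = 0.0015, and adjusted p = 0.816 with an estimated correlation). Its members B2m, the invariant chain of class I molecules, the immunoproteasome subunit Psmb8, and the class I genes H2-D1 and H2-Q7 gave -2.59, -2.23, -2.16 and -2.08 in pair 2, and -0.42, 0.13, 0.16 and 0.08 in pair 1. Class I genes are near-identical in parts, so single members are uncertain. The difference between the pairs, tested by turning the sign of pair 2 (an alternative chosen after seeing the data), passed for both lists at the preset correlation (camera adjusted p = 6.89e-10 and 6.52e-05) and for neither with an estimated correlation (adjusted p = 0.821 for each). In pair 2 the medians were -0.08 for T and NK cell genes (adjusted p = 0.540 over both pairs) and 0.25 for macrophage and myeloid genes (adjusted p = 0.940).

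Of the 29 lists tested, 12 passed, 4 up and 8 down. The remaining 4 shifted down by little, each with adjusted p = 0.816 with an estimated correlation. Ribosomal proteins had medians of -0.15 and -0.02 (adjusted p = 0.00123), with 19 of 39 members lower in both pairs. Rpl22, Rplp0 and Rps12 gave -0.70, -0.38 and -0.37, with 0.18 for another Rplp0 probe. Over the alternatives Rplp0 ran from -1.038 to 0.28 and Rps12 from -0.863 to 0.125, so neither kept its direction. Without the Cy5 array of pair 1, the ribosomal median turned to 0.01 and the call was lost (adjusted p = 0.884). Apoptosis regulators were at -0.06 and -0.14 (adjusted p = 0.00446), with the caspase genes Casp1, Casp9 and Casp12 at -0.46, -0.44 and -0.37 and Bak1 at -0.33. ERBB and MAPK signalling was at -0.05 and -0.08 (adjusted p = 0.0226), where the feedback inhibitor Errfi1 gave -1.09, Grb10 -0.79 with 0.03 for another probe, Erbb2 0.65 and the ligand gene Hbegf 0.53. The call of this list was lost without the Cy5 array of pair 1 (adjusted p = 0.0953). PI3K, insulin and IGF signalling was at -0.08 and -0.03 (adjusted p = 0.0304), where Igfbp3 gave 0.47 and Igfbp7 0.37, against its direction, and Igf2r and Foxo1 gave -0.32 and -0.28. Its call was lost without the Cy5 array of pair 1 (adjusted p = 0.178) or of pair 2 (adjusted p = 0.135). The 17 lists that did not pass had adjusted p from 0.0763 to 0.940. Among them, macrophage and fibroblast genes moved apart in the pairs, at -0.18 and -0.15 in pair 1 and 0.25 and 0.25 in pair 2. With an estimated correlation, no list (0) passed (adjusted p = 0.816 for all called lists except skeletal muscle at adjusted p = 0.864), and fry, which asks whether a list's genes move on balance one way, called only the G1/S list (adjusted p = 0.0419). When the sign of pair 2 was turned, so that mice of opposite genotype stood together, 14 lists passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.821). The 14 held 6 of the 12 (interferon response, antigen presentation, skeletal muscle, G2/M, ribosomal proteins and adipocyte) but not G1/S (adjusted p = 0.601). Calls at the preset correlation thus arise from differences between animals too, and do not by themselves show an effect of genotype.

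**Figure D2:**
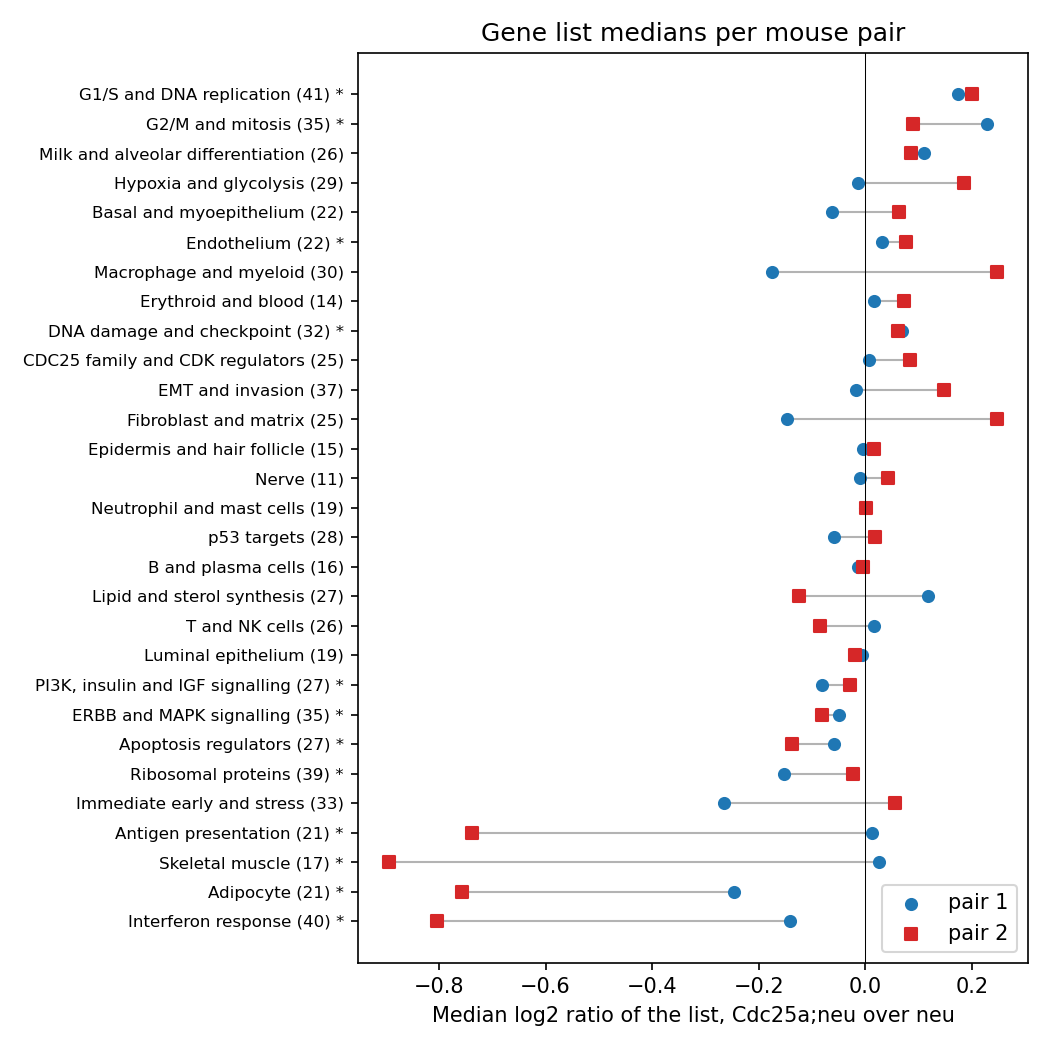
Median log2 ratio of Cdc25a;neu over neu for each gene list in pair 1 (blue circles) and pair 2 (red squares), with the number of measured members in brackets and an asterisk where the camera adjusted p was under 0.05. The G1/S list lies at 0.17 and 0.20, while the skeletal muscle list lies at 0.03 and -0.89.

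Genes that neighbour each other on chromosome 4 were lower in Cdc25a;neu tumours of both pairs. Whether tumours differ by chromosome region was asked because tumours can gain or lose DNA, which was not measured here. Gene order followed GRCm38.p6. Of 259 windows of 10 Mb, 9 passed and all 9 were lower, 5 on chromosome 4 and 4 on chromosome 2. With 5 Mb windows 13 passed as lower and 1 as higher. The 5 windows on chromosome 4 were adjacent and ran from Ror1 to H6pd, with 487 measured genes. Among the brightest tercile of genes, an alternative chosen after seeing the data, the last of them (Rcc2 to H6pd) did not pass, with medians of -0.51 in pair 1 and 0.02 in pair 2 (adjusted p = 0.173). In pair 2, lower values extended beyond them: the window of chromosome 4 from 2610301B20Rik to Atp6v0d2, singled out after its values were seen, was the lowest of that pair at -0.21, against -0.02 in pair 1 (adjusted p = 0.121). The window from Col16a1 to Klhdc7a had medians of -0.25 in pair 1 and -0.15 in pair 2 (camera adjusted p = 9.92e-10, and adjusted p = 0.952 with an estimated correlation), and the window from Edn2 to Adgrb2 had -0.20 and -0.15 (adjusted p = 2.65e-09, and adjusted p = 0.952 with an estimated correlation). In the 5 windows together, 44.8% of genes were lower on all 4 arrays and 8.42% higher on all 4, against 14.1% and 14.5% of other positioned genes. As these windows were picked for being lower, these shares describe them and do not support the shift. Epha2, Tmem82 and Casp9 lie in this region, and so does Rbp7, which was higher. Further members, named after their values were seen, were Padi2 (-1.30), Zbtb40 (-1.15), the mitophagy kinase Pink1 (-1.08), the glucose transporter Slc2a1 (-1.07) and Cited4 (-1.04). The windows on chromosome 2 lay between -0.08 and -0.04 in the mean of the pairs over all genes. The chromosome 4 window from Elavl4 to Hivep3 lay in the same range. Among the brightest tercile, the median was -0.14 on chromosome 2 against -0.43 in the chromosome 4 region, and the 2 chromosome 2 windows that passed there lay at -0.21 (Ehd4 to Pdyn) and -0.17 (Set to Ppp6c). For bright genes in the rest of chromosome 4 the median was -0.153. The region stood apart from that rest in pair 1 (-0.587 against 0.003) but hardly in pair 2 (-0.242 against -0.223). Over all genes, the 4 chromosome 2 windows that passed ran from Set to Ppp6c, Olfr1262 to Api5, Iftap to Lgr4 and Pla2g4b to Tgm3. Chromosome 4 (median -0.06, adjusted p = 2.65e-06) and chromosome 2 (median -0.02, adjusted p = 0.0189) were the 2 of 20 chromosomes that passed as wholes, both with adjusted p = 0.669 with an estimated correlation. With an estimated correlation no window (0) passed (lowest adjusted p = 0.952). With the sign of pair 2 turned, 0 windows passed at the preset correlation.

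**Figure D3:**
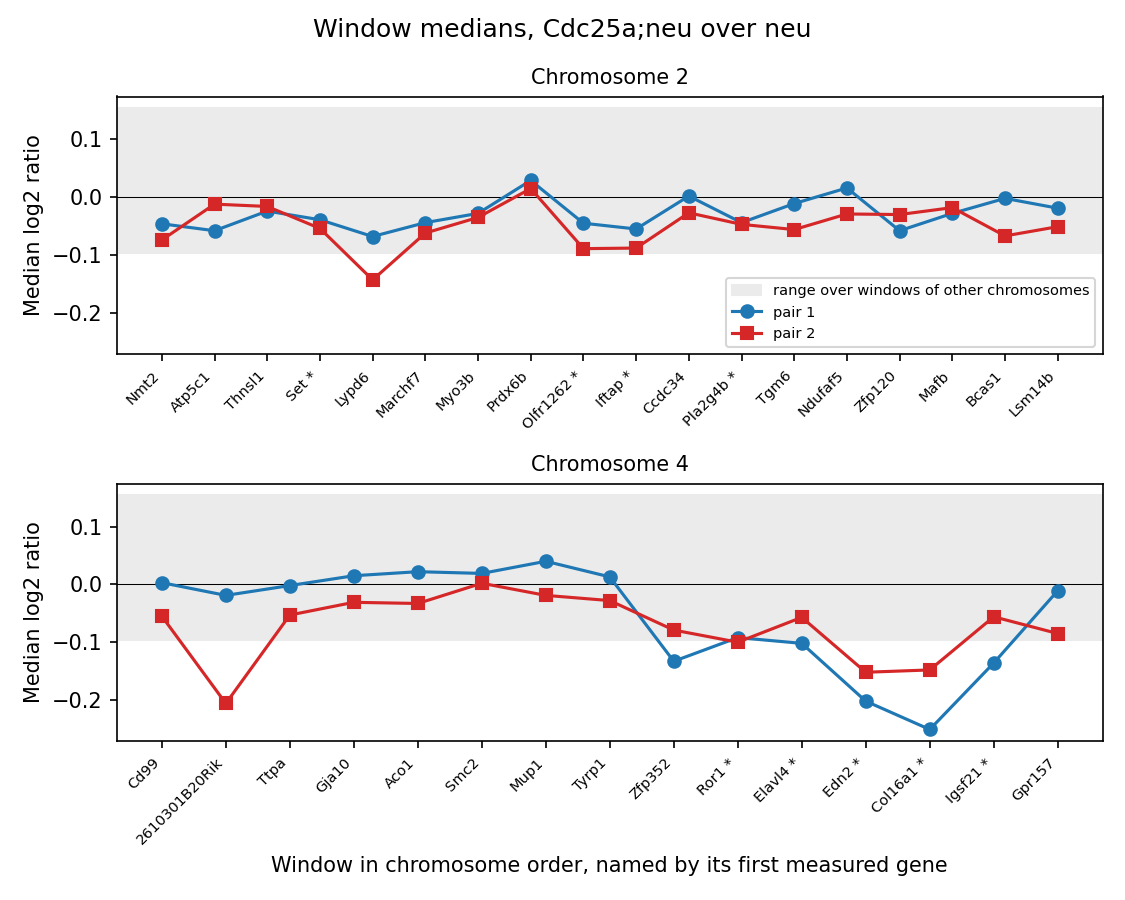
Median log2 ratio of Cdc25a;neu over neu in 10 Mb windows along chromosomes 2 and 4 for pair 1 (blue circles) and pair 2 (red squares), with an asterisk where the camera adjusted p was under 0.05. The grey band gives the range over windows of the other chromosomes, from -0.10 to 0.15, and the window starting at Col16a1 lies at -0.25 and -0.15.

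The pairs resembled each other only in part. Across genes, which are not independent replicates, the log2 ratios of pair 1 and pair 2 had a Pearson correlation of 0.35 and a Spearman correlation of 0.27. At 2-fold or more, 124 genes went the same way in both pairs, 95 higher and 29 lower, and 8 went opposite ways. The same-way count was 189 with the scanner's processed signals and loess and 82 with median centring. The Pearson correlation was 0.241 and 0.191 in these 2 alternatives. The count of opposite-way genes was 42 with the scanner's processed signals and loess, 41 with its log ratio, 32 with the authors' deposited value table and 13 with median centring. Without the near-equal set, 39 went the same way, 10 higher and 29 lower, and the Pearson correlation was 0.27. The opposite-way genes were led by the homeobox gene Hoxa7 (-2.50 in pair 1 and 1.91 in pair 2), the apolipoprotein Apoc1 (2.16 and -1.40), the matrix protein Mgp (-1.34 and 1.32) and the calcium-binding protein S100a6 (-1.30 and 1.96). The 2 dye-swapped arrays of a pair gave sign-turned Pearson correlations of 0.65 (pair 1) and 0.76 (pair 2), and Spearman of 0.33 and 0.55. The SD across genes of their half-difference was 0.10 and 0.11, against 0.22 and 0.29 for the SD of the pair means.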

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

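The alternatives without near-equal genes, without the chromosome 4 region or without genes of any list, with the sign of pair 2 turned, and with the brightest tercile of genes were chosen after seeing the data. With 2 pairs, 0 genes passed in the reported comparison and in most alternatives, which says nothing about stability. Exceptions were median centring with 999 genes (562 higher, 437 lower), the 4 arrays as if independent with 888 (365 higher, 523 lower) and with the pair as a random block with 910 (371 higher, 539 lower). The consensus correlation of that block was -0.01, so it counted the arrays as nearly independent. An unadjusted p under 0.05 gave 3147, and 187 to 3437 over the alternatives that kept the pair or mouse as the unit. Why median centring gave calls was not tested. The random block with a dye term could not be fitted, because 4 arrays are too few for it. Separate-channel values per mouse called 0 genes with and without a replicate block, and 12 lists with the block and 11 without. Without the block the endothelium list (adjusted p = 0.186) and the PI3K list (adjusted p = 0.158) did not pass, and the immediate early list did (adjusted p = 0.0399). The block changed no other list call. Across genes, the difference between mice of one genotype correlated with that of the other at 0.65, where paired mice share arrays.

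Of the 29 gene lists, 12 passed, 9 to 11 when an array was left out and 10 to 12 under the other processing alternatives, not always the 12 reported. With median centring 5 of these were lost (apoptosis, endothelium, ERBB, PI3K and ribosomal) and 3 others gained (CDC25 family, luminal, milk). The ERBB list was also lost with the scanner's processed signals and loess (adjusted p = 0.0506), the PI3K list with the stricter background filter (adjusted p = 0.108), and the endothelium (adjusted p = 0.0662), ERBB (adjusted p = 0.0947) and PI3K (adjusted p = 0.0861) lists with the deposited value table, which gained the immediate early list (adjusted p = 0.00801). With an estimated correlation 0 passed, where camera rests on the spread between 2 pairs and could hardly call any list. With fry 1 passed, and why it called no more was not tested. No called list turned to a call in the other direction. Among the random lists, 11 of the 12 called lists had a median outside the central 95%, and so did 7 lists that were not called. The called list inside it was ribosomal proteins, at percentile 3.085. This check too rests on spread between genes, not between mice. The median kept its direction in 12 of 12 lists without pair 1 and in 10 of 12 without pair 2. For windows, 14 passed at 5 Mb (13 lower, 1 higher), 6 at 20 Mb, 8 with the scanner's own log ratio, 10 without genes of any list, 6 in the brightest tercile of genes and 0 with the sign of pair 2 turned. All 9 kept their direction in either pair alone, where no test could be made.

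The count of genes at 2-fold or more the same way in both pairs was 189 with the scanner's processed signals and loess, 82 with median centring and 39 without near-equal genes. Leaving out an array gave 105 to 141. The count that went opposite ways, 8 as reported, was 42 with the scanner's processed signals and loess, 41 with its log ratio, 32 with the deposited value table, 13 with median centring and 8 to 11 when an array was left out. The correlation of the pairs was 0.24 with the scanner's log ratio, 0.241 with its processed signals and loess, 0.191 with median centring, 0.253 with the deposited value table and 0.27 without near-equal genes, and 0.271 to 0.368 when an array was left out. The cause was not tested, except that the near-equal genes add like ratios to both pairs. Genes at 2-fold or more numbered 261 in the mean and 245 to 505 in a single pair. In the region on chromosome 4 the shift was smaller for dim genes. Its median was -0.43 for genes in the brightest tercile of all positioned genes and -0.02 for those in the dimmest. Why dim genes shifted less was not tested.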

Other observations

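Milk and alveolar genes did not pass as a list (median 0.11, camera adjusted p = 0.270), but did without the Cy5 array of pair 1 (adjusted p = 0.0393), and single members differed widely. Lalba, the alpha-lactalbumin gene, gave -1.33 and Mfge8, a milk fat globule protein, gave 0.74, and both passed when adjusted over the list alone. Csn2, the beta-casein gene, gave 0.57 in pair 1 and 2.34 in pair 2, and Spp1 gave 0.72 and 2.81. In lipid and sterol synthesis (median -0.02, adjusted p = 0.581) Thrsp gave -1.12 and Scd2 0.59. In hypoxia and glycolysis (median 0.07, adjusted p = 0.270) Slc2a1, which lies in the chromosome 4 region, gave -1.07, while Bnip3 gave 0.44. Between the pairs, 1493 genes differed at an adjusted p under 0.05 when the dye swaps served as the only error, which compares these animals and not the genotypes.

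Of the tests in the next 3 paragraphs, those on other probes of the near-equal genes, on the ratio of the pairs and the share of higher genes on chromosome 4, and on endothelial against adipocyte medians were chosen after the result was seen, as were the scanner's log ratio, added once the first value of the copy number test was known, and that test's values per pair. The 141 genes with near-equal ratios may reflect an abundant RNA, higher in both Cdc25a;neu tumours, that binds unrelated probes. Other kept probes existed for 14 of these genes, and their 23 values had a median of 0.012 (bootstrap 95% interval -0.00508 to 0.0399), against 1.31 for the set. Shared regulation is argued against for these 14 genes only, because 0% of these probes reached 0.5 (exact binomial interval 0 to 14.8%). The interval counts probes of one gene as independent. These probes are also the dimmer ones, as the brightest stood for each gene, which weakens this point. Within the quartiles of the set's signal, 1238 other genes had a median of -0.0323, so most genes of like signal did not share the set's ratios. A bias of bright spots stays open, because loess centres ratios near 0 at each signal level, which largely fixed this median in advance. Whether such an RNA exists, and which one it is, stays open, and no biological explanation beyond shared regulation was tested.

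The lower values on chromosome 4 could reflect a smaller number of DNA copies in the Cdc25a;neu tumours, as a hypothesis, but DNA was not measured. In the brightest tercile of the region's genes, 81.5% lay below 0, and the median of the pairs' mean was -0.433 (bootstrap interval -0.485 to -0.373), above the bound of -0.5 set in advance for loss of 1 copy in nearly all cells, or -0.472 (-0.518 to -0.402) with the scanner's log ratio, which the offset of 50 does not compress. Such a loss in both tumours is argued against by pair 2, at -0.257 (-0.314 to -0.152) and -0.268 (-0.33 to -0.159) with the scanner's log ratio. This holds only if the neu tumour of pair 2 kept both copies, because a loss on its side would shrink the ratio. Copy numbers of the neu tumours were not measured. In pair 1, at -0.587 (-0.653 to -0.479), the interval reached above the bound, and at -0.637 (-0.727 to -0.531) with the scanner's log ratio it lay wholly below it. There, loss in nearly all cells and in a share of the cells cannot be told apart. A segment of another mouse strain stays open, because the share of the region's genes higher on all 4 arrays, 8.42% (exact interval 6.11 to 11.2%) against 14.5% elsewhere, decides nothing in windows picked for being lower. A different mix of cell types stays open too: the ratio of the pair 2 to the pair 1 median was 0.567 in the region (0.383 to 0.728) and 3.08 for adipocyte genes, but the latter's interval of 0.575 to 6.59 overlaps it, and in pair 2 bright genes of the rest of chromosome 4 lay at -0.223, against 0.003 in pair 1.

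The lower adipocyte genes might reflect fewer fat cells in the Cdc25a;neu samples. A further list of 21 fat cell genes, 20 of them measured and 0 of these in any other list, gave medians of -0.05 in pair 1 (bootstrap interval -0.154 to 0.155) and -0.154 in pair 2 (-0.631 to -0.043), with 11 genes lower and 5 higher in both pairs. Rbp4, Plin4 and Ces1d gave -1.20, -0.93 and -0.70, whereas Cd36, which endothelium and mammary epithelium also express, gave 0.72. The prediction set in advance for fewer fat cells asked for lower medians than these in both pairs, so it was not met. A median above -0.1 in either pair was to count against it. The pair 1 median lay above this bound, but its interval reached both sides, which left this explanation open. A larger share of tumour cells that lowers every other cell type alike was tested with endothelium only. Its medians lay at 0.032 in pair 1 and 0.076 in pair 2, not below 0. Endothelial medians exceeded adipocyte medians by 0.278 in pair 1 (0.111 to 0.559) and 0.833 in pair 2 (0.206 to 1.39). Part of this gap is built in, because the adipocyte list was picked for being low and endothelium was called as up. The gap thus cannot decide this explanation, which stays open. Fibroblast medians, which the prediction also named, were not tested. Fibroblast and macrophage medians lay below 0 in pair 1 (-0.148 and -0.176), where adipocyte genes lay at -0.246, and above it in pair 2 (0.247 and 0.246). Skeletal muscle lay at 0.026 and -0.894. Whether genotype or dissection set the fat content was not tested.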
